A study of Escherichia coli with 4 samples.

How the data were processed

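The series measured transcript levels of Escherichia coli strain MG1655 in anaerobic chemostats before and during exposure to nitric oxide, on 4 two-colour microarrays. Per the labels, cells grew on 54 mM glycerol with 50 mM fumarate as electron acceptor at a dilution rate of 0.1 per h. One RNA sample was taken before and another 5 min after the nitric oxide donors NOC-5 and NOC-7 were added at 10 uM each. The series text names 2 chemostat runs as biological repeats. Each run gave 2 arrays of the same pair of RNA samples: array 1 carried the exposed sample in Cy5 and the control in Cy3, and array 2, the dye swap, carried them the other way round.

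The deposited table holds 1 value per probe and array, taken here as the log2 ratio of the 2 channels; no source used here states the log base. Base 10 would put the highest ratio beyond the range of a 16-bit scanner, whereas a natural log is not excluded by the values and would multiply every log2 value by one factor and raise every fold to that power. It would also move the counts that use a fixed size (2-fold, treat), but not the p-values of the tests against 0. The background correction, the normalization within and between arrays and the spot filter of the authors are not given in the sources used here. The median over probes was 0.000468 and -0.0168 on arrays 1 and 2 of run 1 and -0.0265 and -0.00606 on arrays 1 and 2 of run 2, so the deposited log2 ratios had already been centred near 0. The 2 arrays of a run correlated positively over genes (Pearson r = 0.25 in run 1 and 0.193 in run 2), so the dye-swap arrays were taken as already turned and no sign was changed. Which channel is on top is not stated. The likely direction is exposed over control, because the highest ratios belong to norV, norW, ytfE and hmp, genes known to be induced by nitric oxide. If the table ran the other way, every sign given for a ratio would turn together.

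Of 4608 probes, 4087 were paired with 1 gene by the platform annotation, 0 with several, and 521 had no name and were left out. The annotation's gene identifiers were looked up in the RefSeq gene table of assembly ASM584v2, which held 4086 of the 4087 and updated the symbol of 197. Coordinates are not given, because the files name no genome build. Probes of 1 gene were averaged on each array. Among 30 genes with several measured probes, the median difference between probes of 1 gene on 1 array was 0.19 on the log2 scale over 77 pairs, and 6 pairs differed by more than 1. Values were empty for 1176 probes on all 4 arrays, and the empty probes of run 1 were the same on both of its arrays, whereas 1754 probes of run 2 had a value on 1 array only. A gene entered the test if each run had a value, which left 1544 of 4038 genes. Of these, 899 were measured on all 4 arrays and 645 on 1 array of run 2, where a dye effect does not cancel in the run's mean.

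Arrays of 1 run hybridise the same RNA and were averaged, giving n = 2 runs. The mean of the 2 run values was tested against 0 with limma 3.58.1 in R 4.3.3 (an intercept in lmFit, then eBayes, two-sided), with Benjamini-Hochberg adjustment over the 1544 genes and a threshold of 0.05 on the adjusted p. The residual degree of freedom per gene was 1 and the prior degrees of freedom were 4.5 with a prior SD of 0.309. The number of arrays and runs limits the precision. On simulated runs of 1544 genes, drawn 20 times, the same test recovered 3.66% of genes changed by a log2 ratio of 0.5, 37.9% of those changed by 1 and 96.1% of those changed by 2, and 153 of its 1978 calls (7.74%) were false. Of the 153, 70 fell on genes with 1 array in run 2, which were 645 of the 1544. The simulation gave the arrays of a run the same values apart from a dye term, with no noise of single arrays and no wider second array. Its rates may therefore not hold for the real arrays.

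Choices made before the data were examined were the design, 26 gene lists drawn from textbook regulons and pathways, the rule for naming genes and most of the alternatives. The rule named up to 15 highest and 15 lowest genes past the threshold with one sign on all arrays, a fixed set (hmp, norV, norW, norR, ytfE, hcp, hcr, ygbA, nrfA, fnr, fur, metE, metA, frdA, narG, soxS, katG, entC, fhuF, iscR and sufA) and up to 4 members of each list past the threshold over all genes or over the list alone. As written the rule asked for one sign on 4 arrays; genes with an empty value were kept if every array with a value had that sign. A direction with fewer than 10 calls would have been filled up to 10, which was not needed. Lists with at least 3 tested members were tested with limma's camera at the preset inter-gene correlation of 0.01, adjusted over lists, with an estimated correlation and fry beside it. Members past the threshold were also counted with p adjusted over the list alone.

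Alternatives were other centrings, quantile normalization, fits of the 4 arrays with the run as a random block with and without a dye term or as independent values, other thresholds, robust eBayes, genes on all 4 arrays, genes whose dye orientations disagreed least, and each run and array left out. Centring each print block of the array, testing lists on genes present on all 4 arrays, testing genes and lists without the second array of run 2, and the estimated correlation in the settings with reduced lists or arrays were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.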

Results

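The response of anaerobic Escherichia coli MG1655, the reference K-12 strain, to nitric oxide was measured in 2 chemostat runs. A chemostat holds growth at a constant rate by a steady feed, so that the culture before the addition serves as its own control. NOC-5 and NOC-7 are compounds that release nitric oxide spontaneously in solution and differ in how fast they do so. Each run contributed an exposed and a control RNA sample, taken 5 min after and just before the addition, on an array and its dye swap. A value was present for 1924 probes (41.8% of 4608) on each array of run 1, and for 2068 (44.9%) and 2422 (52.6%) on arrays 1 and 2 of run 2. The SD of the log2 ratios over the 899 genes on all 4 arrays was 0.491 and 0.493 on the arrays of run 1, 0.585 on array 1 of run 2 and 0.796 on array 2 of run 2. The number of arrays limits the precision.

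The question of the comparison, from the series title, was which transcripts respond to nitric oxide when oxygen is absent. Among the genes that rose were members of iron-sulfur cluster assembly, iron uptake, the cytochrome bd oxidase and sulfate assimilation, and among those that fell were members of nitrite, nitrate and fumarate respiration and of arginine biosynthesis, and the ferritin gene ftnA. Log2 ratios are given as exposed over control, which is the likely direction of the deposited values but is not stated. Of 1544 genes measured in both runs, 29 passed limma's test at an adjusted p under 0.05, 12 higher and 17 lower, with adjusted p from 0.0372 to 0.0442. Each had one sign on all arrays that measured it, and 15 were measured on all 4 arrays, while the rest had 1 array in run 2, where a dye effect does not cancel. For iscR, soxS, exbD, nrfA, upp, glpX, dtpD, argA and preT that array was the second of run 2, whose ratios spread most. Without that array 20 of the 29 could still be tested. The smallest size among them was 1.32 on the log2 scale, and 210 genes had an unadjusted p under 0.05. The calls lay near the threshold, and limma called 0 genes with the median of each array set to 0 (lowest adjusted p = 0.0581, 198 genes at an unadjusted p under 0.05). It also called 0 of 1136 without the second array of run 2 (lowest adjusted p = 0.0754, 122 genes at an unadjusted p under 0.05). The called genes with a value moved by at most 0.019 and 0.49 in the 2 settings, less than their sizes, so each kept its sign. The count was 63 (28 higher, 35 lower) with print-block medians set to 0, 23 (7 higher, 16 lower) after quantile normalization, and 132 with all 4 arrays fitted and the run as a random block, a fit whose within-run correlation was estimated below 0 (-0.441).

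**Figure D1:**
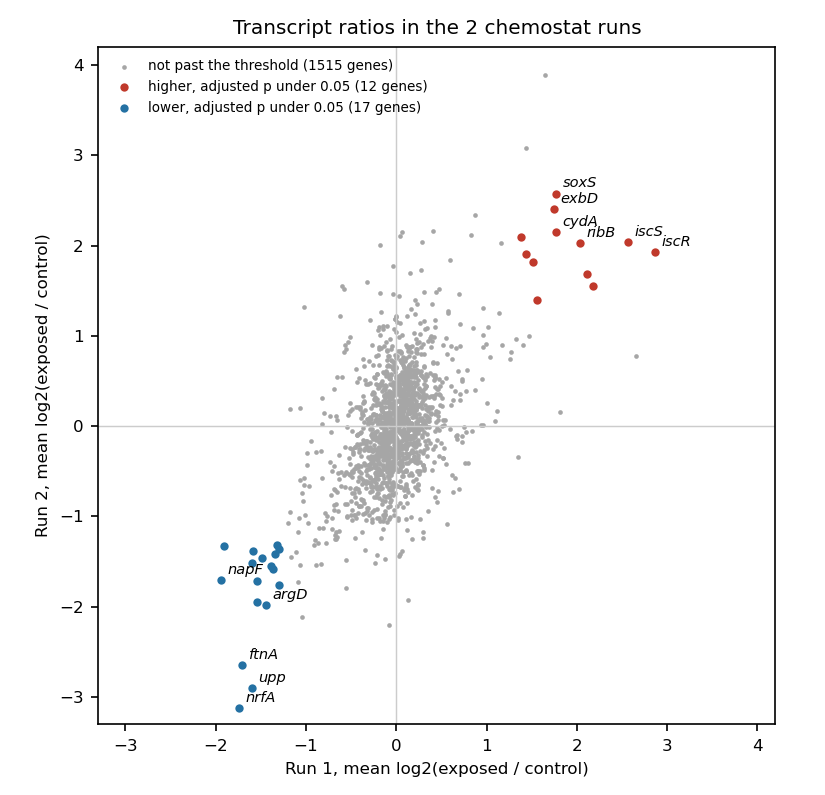
Mean log2 ratio (exposed over control) of each gene in run 1 (x axis) and run 2 (y axis) for the 1544 genes measured in both. Red and blue points are the 12 higher and 17 lower genes past an adjusted p of 0.05, which lie in the upper right and lower left corners.

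Iron-sulfur cluster assembly by the Isc system held the 2 highest values among the genes past the threshold. The operon's regulator iscR (b2531) rose by a mean log2 ratio of 2.40 ± 0.66 (SD, n = 2 runs), a 5.26-fold change (adjusted p = 0.0372). The cysteine desulfurase gene iscS rose by 2.30 ± 0.37, the scaffold gene iscU by 1.90 ± 0.31 and the carrier gene iscA by 1.66 ± 0.21 (adjusted p = 0.0372 for each). All 8 members of the Isc list were above 0 with a median of 1.28, and the list shifted up (camera adjusted p = 3.77e-08; adjusted p = 0.606 with an estimated correlation). Of these, 4 rose over all genes and 6 passed when adjusted over the list alone. Neighbouring genes of an operon are not independent members, which the preset correlation of 0.01 does not allow for. The Suf system, the alternative assembly pathway, was also shifted up (camera adjusted p = 0.0019; adjusted p = 0.606 with an estimated correlation). Its 3 tested members were above 0 with a median of 0.92, none passed over all genes and all 3 passed when adjusted over the list alone. Values in that group were 1.14 ± 0.26 for sufA, 0.92 ± 0.30 for sufD and 0.63 ± 0.33 for sufC (n = 2 runs). In run 2 sufA and sufD were measured on the second array only, and sufC was at 0.0089 on the first. The Suf list could therefore not be tested without the second array of run 2.

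Of the iron uptake and iron storage genes tested, exbD and ftnA passed over all genes within their lists. The gene exbD, part of the energy-transducing complex of outer-membrane siderophore uptake, rose by 2.07 ± 0.47 (SD, n = 2 runs, adjusted p = 0.0372), and its partner tonB had a value of 1.60 ± 0.62 (adjusted p = 0.0641). In the list of iron uptake genes regulated by Fur, the ferric uptake repressor, 6 of 7 tested members were above 0 with a median of 0.74 (camera adjusted p = 1.04e-04; adjusted p = 0.606 with an estimated correlation). In it 1 rose over all genes and 4 passed when adjusted over the list alone. Another 22 members were measured in 1 run only, 17 of them above 0. On the 3 members measured on all 4 arrays, the median ran from 0.0359 on array 1 of run 1 to 1.52 on array 2 of run 2. The ferric-siderophore reductase gene fhuF had a value of 1.47 ± 0.91 (adjusted p = 0.132), the enterobactin gene entC 0.64 ± 0.54 (0.367), fepB 0.74 ± 0.31 (0.234), and fur itself 0.27 ± 0.25 (0.578), with 0.717 on the second array of run 2 and 0.173 at most on the others. The ferritin gene ftnA, an iron store, fell by 2.18 ± 0.67 on the log2 scale (4.53-fold, adjusted p = 0.0372). The gene bfd, the ferredoxin that acts in iron release from bacterioferritin, had a value of 2.77 ± 1.58 (adjusted p = 0.0839), its runs lying far apart. The iron storage and manganese uptake list, with 7 tested members and a median of 0.02, did not shift (camera adjusted p = 0.88). In it 1 gene fell over all genes, and 1 higher and 1 lower passed when adjusted over the list alone.

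Genes of nitrite, nitrate and fumarate respiration were among those that fell. The gene nrfA (b4070), which encodes the periplasmic nitrite reductase, fell by 2.43 ± 0.98 on the log2 scale (SD, n = 2 runs, 5.40-fold, adjusted p = 0.0407), and nrfB, its electron donor, fell by 1.53 ± 0.33 (adjusted p = 0.0405). The gene napF of the periplasmic nitrate reductase operon fell by 1.82 ± 0.17 (adjusted p = 0.0372). In the fumarate reductase operon frdB fell by 1.48 ± 0.15 (adjusted p = 0.0372) and frdC by 1.33 ± 0.04 (adjusted p = 0.0426), with frdA at -1.13 ± 0.06 (adjusted p = 0.0699). In the list of genes activated by FNR, the anaerobic regulator, 33 of 39 tested members were below 0 with a median of -0.78 (camera adjusted p = 6.05e-09; adjusted p = 0.606 with an estimated correlation). Over all genes 4 fell and 3 rose, and 22 lower and 4 higher passed when adjusted over the list alone. The list shares members with the fumarate and nitrate lists, and over members that no other list holds its median was -0.34 (camera adjusted p = 0.0301; adjusted p = 0.582 with an estimated correlation). The members that rose were feoA of ferrous iron uptake and cydA and cydB, the subunits of the cytochrome bd oxidase, which is known to be repressed by FNR at the lowest oxygen levels although the list, as fixed, holds both genes. The means were 1.74 ± 0.50 for feoA (adjusted p = 0.0405), 1.96 ± 0.27 for cydA and 1.67 ± 0.33 for cydB (adjusted p = 0.0372 for both).

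The fumarate respiration list had all 7 tested members below 0 with a median of -1.33 (camera adjusted p = 9.50e-08; adjusted p = 0.606 with an estimated correlation). Of these 2 fell over all genes, and all 7 passed when adjusted over the list alone. The C4-dicarboxylate carriers dcuB and dcuC in it were at -1.58 ± 0.76 and -1.41 ± 0.45 (adjusted p = 0.0867 and 0.0641). In the nitrate and nitrite list 10 of 14 tested members were below 0 with a median of -0.72 (camera adjusted p = 1.04e-04; adjusted p = 0.606 with an estimated correlation). In it 3 fell over all genes and 7 were lower when adjusted over the list alone. Members measured on all 4 arrays had a median of -0.12, and on those genes alone the shift did not pass (adjusted p = 0.0747). Without the second array of run 2 the median was -0.40 (camera adjusted p = 0.0263; adjusted p = 0.699 with an estimated correlation). In that list narH, a subunit of the membrane nitrate reductase, was at -1.11 ± 0.28 (adjusted p = 0.0881), and nrfC at -1.08 ± 0.25 (0.0887).

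Glycerol use, the only carbon and energy supply of these cultures, was represented by 10 tested genes, 8 of them below 0 with a median of -0.52 (camera adjusted p = 0.0019; adjusted p = 0.606 with an estimated correlation). Of these, 1 fell over all genes and 3 were lower when adjusted over the list alone. The gene glpX, a fructose bisphosphatase in the glycerol operon, fell by 1.74 ± 0.28 (adjusted p = 0.0372), and glpC and glpT, of the anaerobic dehydrogenase and the glycerol phosphate carrier, were at -1.18 ± 0.49 and -0.83 ± 0.33 (adjusted p = 0.101 and 0.188). Without the second array of run 2 the list no longer passed (adjusted p = 0.282, median -0.42). ATP synthase had all 8 tested genes below 0 with a median of -0.66 (camera adjusted p = 1.04e-04; adjusted p = 0.606 with an estimated correlation). None passed over all genes and 4 passed when adjusted over the list alone. The values of atpA, atpH, atpE and atpF were -0.79 ± 0.21, -0.76 ± 0.39, -0.72 ± 0.38 and -0.72 ± 0.21, and atpH stood apart at -1.7 on the second array of run 2. Ribosomal protein genes were below 0 for 38 of 41 with a median of -0.38 (camera adjusted p = 4.87e-07; adjusted p = 0.606 with an estimated correlation). None of them passed over all genes or over the list alone. Both groups were lowest on the second array of run 2. On genes measured on all 4 arrays the medians there were -1.44 for ATP synthase and -0.887 for ribosomal proteins, against -0.175 and -0.232 on the first array of that run. Without the second array of run 2 the list medians were -0.36 for ATP synthase (camera adjusted p = 0.0027) and -0.26 for ribosomal proteins (1.58e-04), with adjusted p = 0.699 for both with an estimated correlation.

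In sulfur assimilation 1 gene passed over all genes. The gene cysD, a subunit of sulfate adenylyltransferase, rose by 1.48 ± 0.12 (SD, n = 2 runs, adjusted p = 0.0372), and its neighbour cysN had a value of 1.13 ± 0.24 (adjusted p = 0.0839). In the cysteine list 10 of 11 tested members were above 0 with a median of 0.58 (camera adjusted p = 4.87e-07; adjusted p = 0.606 with an estimated correlation). Of them 1 rose over all genes and 5 passed when adjusted over the list alone. The sulfate carriers cysP and cysU were at 1.06 ± 0.05 and 0.99 ± 0.04 (adjusted p = 0.0839 and 0.0908). In the copper and zinc list all 6 tested genes were above 0 with a median of 0.24 (camera adjusted p = 0.0167; adjusted p = 0.606 with an estimated correlation). None passed over all genes and 2 passed when adjusted over the list alone. Another 10 members were measured in 1 run only, 4 of them above 0. Over the 4 members on all 4 arrays the median was -0.016 and -0.101 with the exposed RNA in Cy5, against 0.689 and 0.741 in Cy3. The copper exporter copA and the copper oxidase cueO had values of 2.26 ± 1.16 and 1.61 ± 1.03 (adjusted p = 0.0742 and 0.131). The copper and zinc call was lost with print-block medians set to 0 (adjusted p = 0.0701) and without the second array of run 2 (adjusted p = 0.146).

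Single genes past the threshold outside these groups were soxS, the activator of the superoxide response, ribB of riboflavin biosynthesis and aroF, which begins aromatic amino acid synthesis. They rose by 2.17 ± 0.57, 2.03 ± 0.0039 and 1.87 ± 0.45 (SD, n = 2 runs, adjusted p = 0.0372 for each). The small SD of ribB is that of 2 run averages, while its single arrays ran from 1.26 to 2.80. On the lower side, upp, a uracil salvage enzyme, fell by 2.25 ± 0.92 (adjusted p = 0.0442), and preT, a subunit of a dihydropyrimidine dehydrogenase, fell by 1.38 ± 0.05 (adjusted p = 0.0405). The arginine biosynthesis genes argD, argB and argA fell by 1.71 ± 0.38, 1.56 ± 0.06 and 1.47 ± 0.02 on the log2 scale (adjusted p = 0.0372). The gene ubiU, for oxygen-independent ubiquinone synthesis, fell by 1.63 ± 0.12, ynjA by 1.62 ± 0.41 (adjusted p = 0.0405), the peptide carrier gene dtpD by 1.48 ± 0.15 and bidA by 1.47 ± 0.12, with -1.7 on the first array of run 2 apart from the others.

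**Figure D2:**
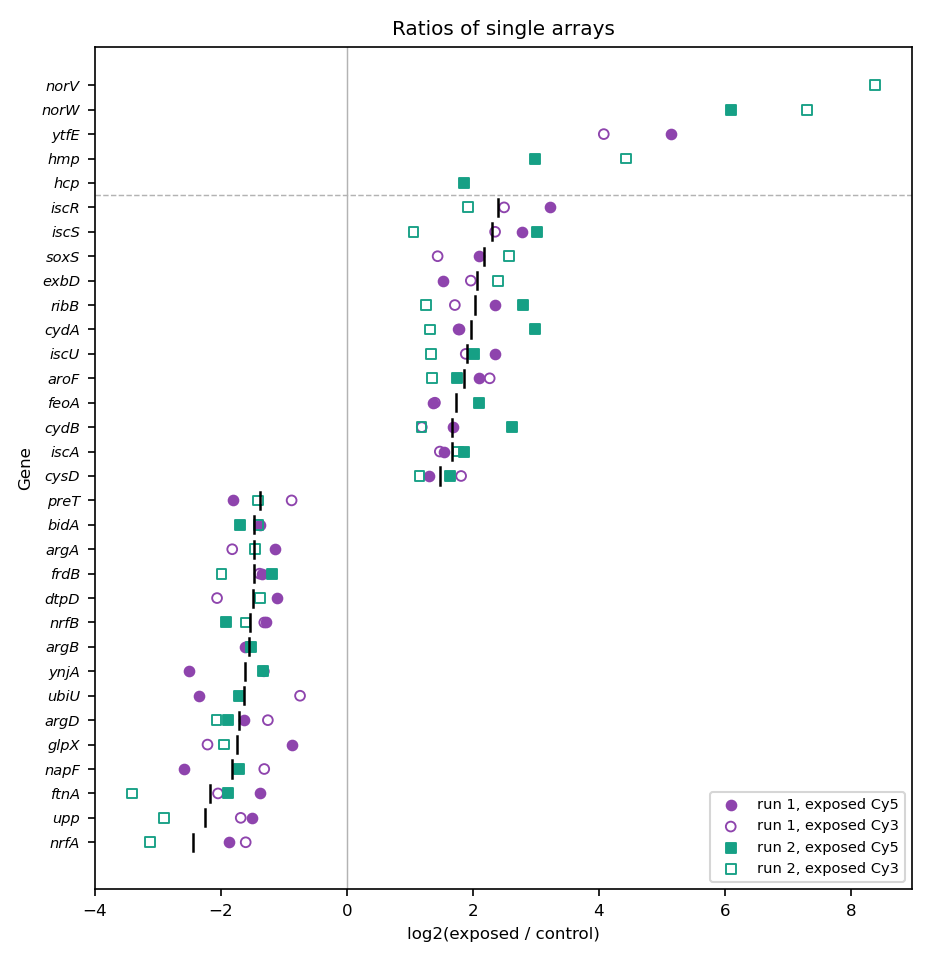
Log2 ratio (exposed over control) on single arrays, with circles for run 1 and squares for run 2, filled where the exposed RNA carried Cy5; black bars mark the mean of the 2 runs. Below the dashed line are the 12 higher and 15 lowest genes past the threshold, above it are norV, norW, ytfE, hmp and hcp, measured in 1 run only, with norV at 8.38 on its single array.

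Genes known for nitric oxide defence included the highest ratio of each array but entered no test, because norV, norW, ytfE, hmp and hcp had values in 1 run only. The flavorubredoxin gene norV was measured on 1 array of run 2 at a log2 ratio of 8.38, and norW, its reductase, on both arrays of run 2 at 6.09 and 7.30. The iron-sulfur repair gene ytfE was measured on both arrays of run 1 at 5.15 and 4.08, the flavohaemoglobin gene hmp on both arrays of run 2 at 2.98 and 4.43, and the hybrid cluster gene hcp on 1 array of run 2 at 1.86. The regulator gene norR, the hcp partner hcr and the methionine gene metA had no value on any array, and fnr and narG had 1 value each, 1.46 and -1.35, on 1 array of run 2. The list of genes regulated by NorR had 2 members with values in 1 run, both above 0, and none tested. In the list regulated by the nitric oxide sensor NsrR, 10 members were tested. Of these 2 fell over all genes, nrfA and nrfB, both also in the FNR list. In it 1 higher (ygbA, 1.19 ± 0.08, adjusted p = 0.0633) and 3 lower passed when adjusted over the list alone. Its median was 0.17, its mean -0.25 and the direction of its test down, with no shift (camera adjusted p = 0.88). With members that belong to no other list, which leaves out the nrf genes, the median was 0.59 and the list shifted up (camera adjusted p = 0.00694; adjusted p = 0.582 with an estimated correlation). Over the 6 NsrR members on all 4 arrays the median was 0.904 on the second array of run 2, against 0.0343, 0.16 and 0.163 on the others.

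Other stress and metabolic lists showed no shift by camera. The SoxRS list had 12 tested members with 1 higher over all genes and over the list alone, soxS, and a median of 0.03 (camera adjusted p = 0.432). The OxyR list had 7 members with a median of 0.27 (camera adjusted p = 0.286), and the catalase gene katG had a value of -0.16 ± 0.12 (adjusted p = 0.721). The OxyR median was 0.00016 in run 1 and 0.45 in run 2. Several lists had medians of opposite sign in runs 1 and 2. These were 0.12 and -0.38 for phage shock, 0.24 and -0.36 for acid resistance, and -0.07 and 0.22 for methionine biosynthesis. They were 0.05 and -0.03 for SOS and -0.06 and 0.07 for global regulators. Among lists named above they were -0.19 and 0.49 for NsrR and 0.01 and -0.03 for iron storage and manganese uptake. Methionine biosynthesis, where 7 of 9 tested genes were above 0, had a median of 0.16 (camera adjusted p = 0.156) and metE a value of 0.76 ± 0.29 (adjusted p = 0.216). Medians were 0.09 for 15 heat shock genes (camera adjusted p = 0.314), -0.06 for 10 SOS genes (0.879), -0.12 for 4 phage shock genes (0.721), -0.06 for 5 acid resistance genes (0.961), 0.18 for 18 general stress genes (0.265) and 0.31 for 7 flagellar and chemotaxis genes (0.119). The heat shock list passed only without the second array of run 2 (camera adjusted p = 0.0414, median 0.23; adjusted p = 0.699 with an estimated correlation). Aerobic respiration and the TCA cycle had a median of -0.14 over 21 genes (camera adjusted p = 0.119), and hydrogenases and formate metabolism -0.15 over 16 genes (0.361). None of these last lists, from OxyR to hydrogenases, had a member past the threshold over all genes or over the list alone. Among 16 global regulators iscR rose over all genes, and arcA, the aerobic respiration regulator, was lower when adjusted over the list alone at -1.21 ± 0.45 (adjusted p = 0.0887). The median of that list was -0.06, its mean 0.05 and the direction of its test down, with no shift (camera adjusted p = 0.961). In all, 11 of 25 tested lists shifted with the preset correlation, 5 up and 6 down. With an estimated correlation 0 did (0 at an unadjusted p under 0.05) and with fry 0 did (2 at an unadjusted p under 0.05). Both of these tests rest on 1 residual degree of freedom, so they had little power and cannot decide the question. The shifts by camera hold only under the preset correlation. That preset, 0.01, treats members as nearly independent, whereas genes less than 50 bp apart shared their mean ratio (r = 0.894 over 145 pairs). For lists of neighbouring genes, such as Isc and ATP synthase, the p-values by camera may therefore be too low.

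**Figure D3:**
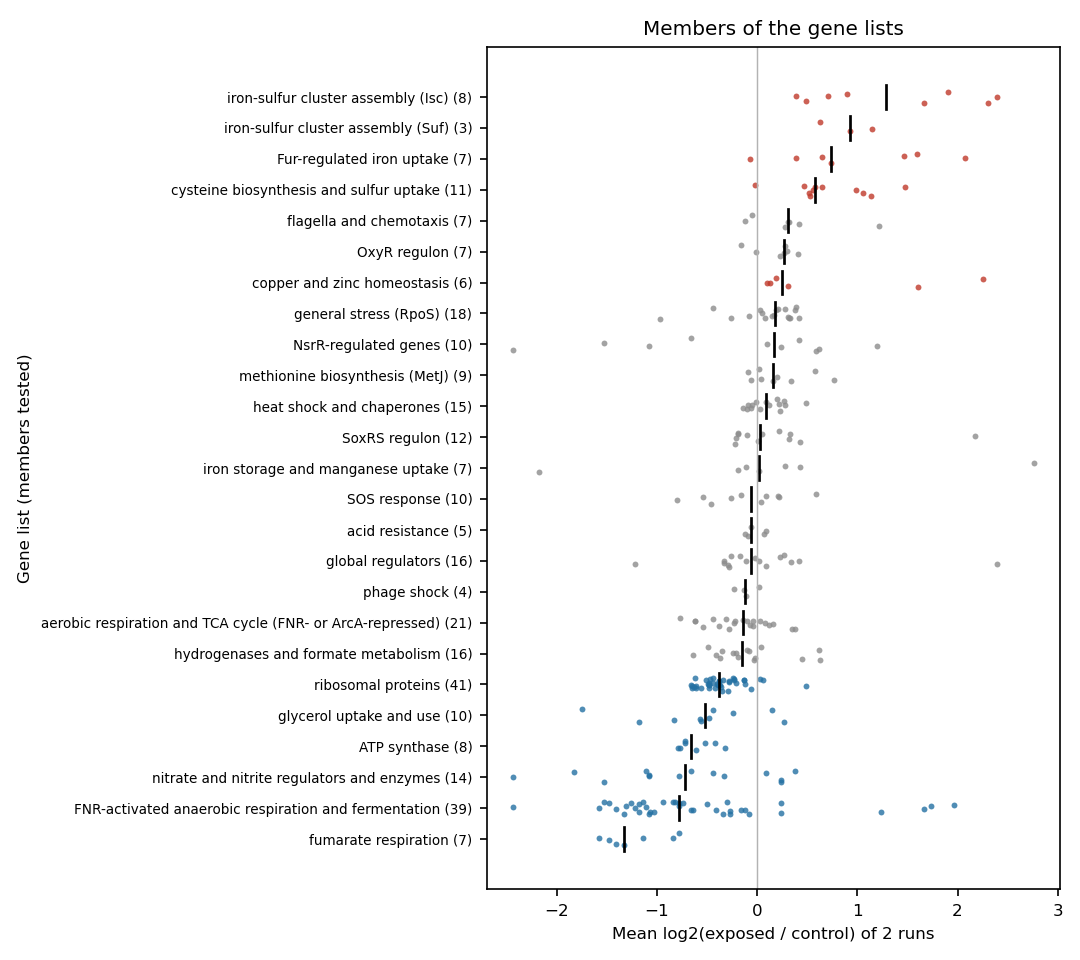
Mean log2 ratio of the 2 runs (exposed over control) for each tested member of the 25 gene lists, with the black bar at the list's median and the number of tested members in brackets. Red lists shifted up, blue lists down and grey lists did not shift by camera with the preset correlation, the Isc list lying highest with a median of 1.28 and the fumarate respiration list lowest with -1.33.

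How far the repeats agreed was asked of the run means and the single arrays. Across the 1544 genes the run means correlated with Pearson r = 0.546 and Spearman rho = 0.436, and 65.3% of genes had one sign in both runs; genes are not independent replicates. Arrays of one dye orientation in different runs correlated more (rho = 0.589 with the exposed RNA in Cy5 and 0.419 in Cy3) than the arrays of one run (rho = 0.0238 in run 1 and 0.0527 in run 2). A dye effect, tested by limma on the 899 genes of all 4 arrays, was called for 44 genes (lowest adjusted p = 3.95e-07). The same fit for the exposure called 110 of the 899 by limma (lowest adjusted p = 2.67e-25). The test over 1544 genes called 15 of those 899 from the same values, so the 110 depends on which genes were fitted. Each gene had 1 residual degree of freedom, so a p as low as 2.67e-25 by limma rests mostly on a variance pooled over genes. The count of 110 is therefore no firmer than the main count. Between runs the SD of the called genes ran from 0.0039 for ribB to 0.66 for iscR among the 12 higher genes, and from 0.017 for argA to 0.98 for nrfA among the 15 lowest. These SDs are of run averages and leave out the spread of single arrays, which ran from 1.26 to 2.80 for ribB and from -1.82 to -1.15 for argA.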

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

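Of the tests in this part, those of a looser spot filter and of a stronger response in run 2 were chosen only after the result was seen. With Dixon's test over the 4 arrays, 34 values were tested and 3 had an array far from the others; chance alone marks about 1 in 20. The ATP synthase gene atpH was at -1.7 on the second array of run 2, with the other arrays from -0.567 to -0.379. The Fur regulator gene fur was at 0.717 on the same array, with the others from 0.0816 to 0.173. The gene bidA was at -1.7 on the first array of run 2, with the others from -1.4 to -1.37.

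The second array of run 2 carried 2 of these values and had the widest log2 ratios, with an SD of 0.796 over the 899 genes on all 4 arrays against 0.585 on the first array of that run. The ratio of the 2 SDs on the genes present on every array was 1.36 (95% bootstrap interval 1.26 to 1.47). The wider spread was thus not limited to genes that only the second array kept. A looser spot filter on that array stays open, since it could also keep poor spots of genes present on every array. A stronger response in run 2, the biological explanation, would act on both arrays of the run, which carry the same RNA pair. By design it cannot alone widen 1 of them, but the SD ratio is the observed pattern itself and tests nothing further. Whether run 2 responded more strongly than run 1 stays open. Array 1 of run 2 (0.585) also spread more than the arrays of run 1 (0.491 and 0.493). The slopes on the run 1 mean were 0.848 and 0.923 for arrays 1 and 2, both below 1, but noise in the run 1 mean lowers such slopes. Their difference of 0.0748 (interval -0.08 to 0.252) was the comparison first chosen, and it decided nothing. The SD ratio was used in its place after the result was seen. Independent spot noise stays open, since the array's deviation from the other 3 correlated between neighbouring genes with r = 0.279 (0.132 to 0.43), against 0.27 for the first array of that run, and that deviation also holds the difference between runs.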

How the results depend on the processing

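The print-block centring, the lists on genes present on all 4 arrays, the genes and lists without the second array of run 2, and the estimated correlation in the settings with reduced lists or arrays were chosen after seeing the data. All 29 called genes kept their sign in every setting that measured them. Their sizes were at least 1.32 and no setting moved any of them by more than 0.69, so no sign could turn. The count of calls moved, and the cause was not tested. Calls were 63 (28 higher, 35 lower) with print-block medians set to 0, 132 (48, 84) with 4 arrays and the run as a random block (within-run correlation -0.441), 129 (51, 78) with a dye term added (-0.0939), 69 (30, 39) with 4 independent arrays, 66 (31, 35) at an unadjusted p under 0.05 with 2-fold size and 110 (40, 70) of 899 genes present on all 4 arrays. All 29 were among the first 5 of these, and 15 of the 15 tested were among the last (lowest adjusted p = 2.67e-25 by limma). For the unadjusted p with 2-fold size this holds by definition, since every called gene meets both conditions. The lowest adjusted p on the 899 genes rests mostly on a variance pooled over genes, since each gene had 1 residual degree of freedom. limma called 0 (0 higher, 0 lower) with each array's median set to 0 (198 at an unadjusted p under 0.05), and 0 with treat against a log2 ratio of 0.5 (lowest adjusted p = 0.101, 73 unadjusted). Median centring moved no called value by more than 0.019 but brought the lowest adjusted p to 0.0581. Quantile normalization gave 7 higher and 16 lower genes, 19 of the 29 among them. Leaving out an array or a run gave 0 to 105 calls, 0 to 52 higher and 0 to 53 lower: 105 without array 1 and 79 without array 2 of run 1, 33 without array 1 and 0 without array 2 of run 2 (122 unadjusted), and, with no test, 38 and 43 genes of at least 2-fold on both arrays in run 2 and run 1 alone. Robust eBayes (36), 2-fold size in both runs (42) and leaving out the tenth with most dye disagreement (25) stayed within 1.5 times. Lists shifted were 0 with an estimated correlation (0 unadjusted) and 0 with fry (2 unadjusted), where 1 residual degree of freedom leaves little power. They were 9 to 11 otherwise. Without shared members the NsrR list, unshifted in the main test, shifted up by camera, its median going from 0.17 to 0.59. The correlation of runs was 0.69 on genes of at least 2-fold in either run and 0.66 on genes on all 4 arrays, and 24 genes had a dye effect with print-block centring. A ratio already pairs exposed and control RNA on each array, so the main test was itself paired by run and no separate paired analysis was run. The trend of eBayes on mean intensity was not run, since the table holds no intensities; signal over background is therefore unknown.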

Other observations

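Of the tests in this part, the gene lists and the tests of print-block offsets and of unturned dye-swap arrays were chosen only after the results were seen. Of 9 tested arginine biosynthesis genes 8 were below 0 with a median of -1.31, and argA, argB, argC and argD fell over all genes. Of 12 tested genes of pyrimidine metabolism 11 were below 0 with a median of -0.60, and upp and preT fell over all genes, with preA, the partner of preT, at 0.39. Both lists were drawn up after those genes were seen to be low, so no set test is given for them. In glycolysis 11 of 12 genes were below 0 with a median of -0.44, none past over all genes and 3 over the list alone (camera adjusted p = 8.54e-04 over 12 lists; adjusted p = 0.53 with an estimated correlation). The genes gapA and tpiA were at -0.90 and -0.87. Purine biosynthesis had a median of -0.27 (camera adjusted p = 0.0242, and 0.53 with an estimated correlation). The adjustment ran over all 12 lists, including those for which no set test is given here. Their low p-values by camera lower the adjusted p of glycolysis and purine biosynthesis, so neither is taken as a shift. In cytochrome bd with its assembly genes, cydA and cydB rose, and appC, cydC and cydD were at 0.37, 0.27 and -0.07. In the periplasmic nitrate reductase list 4 of 5 tested genes were below 0 with a median of -0.44, and napF fell over all genes. No set test is given for that list, because napF had been called before it was drawn up. Lists for branched-chain amino acids (camera adjusted p = 0.215), riboflavin (0.307), lysine and threonine (0.415), molybdenum cofactor (0.415), histidine (0.889) and aromatic amino acids (0.936) did not shift; the last 2 had medians below 0 and means and tests above it. In riboflavin synthesis ribB rose and the other 3 tested genes lay between -0.22 and 0.09.

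Some of the highest and lowest ratios belonged to genes measured in 1 run only, for which no test was possible. On both arrays of that run, 6 of 690 such genes were at least 4-fold from 0, 4 higher and 2 lower. Besides norW, ytfE and hmp these were ilvN of branched-chain amino acid synthesis (2.21 and 3.08 in run 1), the acetate kinase gene ackA (-2.02 and -2.39 in run 2) and ydjX (-2.62 and -3.55 in run 2). The NADH dehydrogenase gene ndh, repressed by FNR, was at 3.52 and 1.45 in run 2, and grcA, a spare part of pyruvate formate-lyase, at 2.12 and 1.71. These genes were chosen after their values were seen.

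A hypothesis was that the whole arginine pathway was lower, beyond the 5 genes first seen. The median of the 4 remaining tested genes was -0.33 (argE -0.18, argF 0.04, argH -0.48, carB -0.88), which lay between the bounds set beforehand, so whether the pathway as a whole moved may not be settled by these genes.

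Arrays of one dye orientation agreed better than arrays of opposite orientation, those of one run included, with mean Spearman correlations of 0.504 and 0.0708. Dye-swap arrays left unturned are argued against: genes less than 50 bp apart shared the mean of the 4 arrays (r = 0.894 over 145 pairs) more than the dye component (r = 0.286), a difference of 0.608 (95% bootstrap interval 0.425 to 0.779). Offsets between print blocks are consistent with part of it, since the block explained an adjusted R2 of 0.237 of the dye component and 0.00702 of the array mean, with 0.0107 as the 95th percentile of shuffled blocks. As the whole cause they are argued against, because the excess was 0.277 with print-block medians set to 0, against 0.433 as deposited. Single genes also differed by dye: limma called a dye effect for 44 of 899 genes, and for 24 with print-block medians set to 0, and the dye component correlated between runs with r = 0.432. How much of the excess these genes account for was not tested, and no biological explanation was tested.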
